A study of Mus musculus with 12 samples.

How the data were processed

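RNA was taken from 12 mammary tumours grown from 4T1 cells, 3 different tumours in each of 4 groups per the labels' protocols, with a total RNA kit from Omega Bio-tek, and polyadenylated RNA was sequenced by Novogene. The deposited table gives TPM, a length-normalized abundance, for 23667 gene symbols, with 1 column per library. Per the submitters' processing notes, kallisto and the mouse build GRCm38 were used. The version of kallisto, its transcript set, how transcripts were summed to symbols and whether strand was used are not given in the sources used here. Each column sums to the same total, so the TPM values carry no depth, and no counting interval is given for any of them. Because TPM is a share of a library, a large change of a few abundant transcripts shifts all others. Of the symbols, 22923 (96.9%) matched 1 gene of the GENCODE M21 annotation of GRCm38, which supplied coordinates.

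Libraries were grouped by their titles, and every library was compared with every other before averaging. The robust SD of the log2 ratio over genes above 300 TPM was 0.0616 between KO-IgG replicates 2 and 3 and 0.0377 between KO-ICB replicates 1 and 2, against 0.224 to 0.670 for the other 10 pairs within groups. An estimate of the part beyond sampling noise, from a fit of the variance on the inverse of TPM times transcript length, was 0.0421 and 0.0184 for those pairs and 0.209 to 0.625 for the others. Although the labels say that each library is another tumour, each of these pairs was replaced by its mean TPM and counted as 1 sample, which leaves 10. The bound of 0.1 on that SD was set after the pairs had been seen, and the design fixed beforehand had named 12 libraries, so results over the 12 libraries are given too. P-values of the main results measure the spread between these 10 samples, and those over the 12 libraries the spread between tumours as the labels define them.

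Genes with at least 1 TPM in at least 3 of the 12 libraries were tested (13886 genes) on log2(TPM + 1), so a fold change of a low gene is understated. Linear models with 4 group means were fitted in limma 3.58.1 (R 4.3.3) with an intensity trend and robust variance shrinkage, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. All groups share 1 estimate of the spread, so each library enters every comparison through it. The comparisons were KO against CTRL under each treatment and averaged over both, ICB against IgG within each genotype, and the interaction. A few values were compared with exact two-sided permutation tests. The same models were tested on simulated data with the real means and spreads and 200 changed genes. They recovered 70.7%, 70.5%, 81.2%, 57.0%, 18.2% and 91.9% of genes changed by 4-fold for KO-IgG against CTRL-IgG, KO-ICB against CTRL-ICB, CTRL-ICB against CTRL-IgG, KO-ICB against KO-IgG, the interaction and the average, over 13886 genes. For genes changed by 2-fold the shares were 9.1%, 7.6%, 16.9%, 4.2%, 0.3% and 42.2%. Of the genes called, 5.22% to 6.34% were unchanged ones, and 10.2% for the interaction, against a threshold of 0.05. Each gene was drawn independently, with the same spread in all groups, so these shares may differ in real tumours.

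Before the data were examined, 36 gene lists (pathways, cell types, other tissues and RNA quality) were fixed, with the comparisons, the tests and most alternatives, and 35 lists had the 5 tested members required. Lists were tested with camera at a preset correlation of 0.01, and camera with an estimated correlation and fry are given beside it. Where leaving out a tumour leaves 1 in a group, that tumour is assumed to vary like the other groups, and the list p is at the preset correlation. No called list differed in sign between its median, its mean and its test. Genes are named by a rule fixed beforehand: Trex1, up to 10 genes with the largest rise and fall among those past the threshold whose groups do not overlap (the 5 with the smallest p where none passes), and up to 4 members with the smallest p of each list called or holding a called gene. That rule gave more genes than are named, and outside the averaged comparison only Trex1, the first part and members of the interferon list and of lists that held with an estimated correlation or by fry were kept, a limit set after an account of all of them had been seen. A further gene that the rule names is not reported here. Genes named for single libraries (Epcam, Krt8, Isg15, Acta1 and the like) were chosen after their values were seen. The correlations of effects between comparisons were set against 100 simulated groups without an effect, in which each gene was drawn independently.

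Alternatives fixed beforehand were quantile normalization, median centring, limma without trend and robust shrinkage, no filter or a filter of 5 TPM, a pseudocount of 0.1, array weights, only the groups compared, the replicate number as a block, and leaving out each replicate in turn. Those added later were the 12 libraries counted separately, leaving out the control libraries with skin transcripts, leaving out an averaged pair, the block over 12 libraries, and leaving out mitochondrially encoded genes. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.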

Results

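Gene expression was measured by RNA-seq of polyadenylated RNA from mouse mammary tumours grown from 4T1 cells, a mouse mammary carcinoma line. The tumours carried either control cells (CTRL) or cells in which TREX1, an exonuclease that degrades DNA in the cytosol, had been depleted with CRISPR-Cas9 (labelled TREX1 KO). Mice received checkpoint antibodies (ICB, 200 ug anti-PD1 and 100 ug anti-CTLA4, 3 times weekly for 1 week) or matched isotype antibodies (IgG), which gave 4 groups of 3 libraries. The design asks how depletion of TREX1 changes gene expression of the tumour, and how checkpoint antibodies change it with and without TREX1. Values are TPM, the abundance of each transcript scaled to the same total in every library, which keeps no record of read numbers, so the depth behind each value is unknown. KO-IgG replicates 2 and 3, and KO-ICB replicates 1 and 2, differed by little more than an estimate of sampling noise, and each pair was counted as 1 sample by its mean. The comparisons below therefore rest on 10 tumours, 3 in each CTRL group and 2 in each KO group, and counts over the 12 libraries are given beside them.

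Trex1 transcript was higher, not lower, in the libraries labelled TREX1 KO. Trex1 (GRCm38 chromosome 9, 109057933 to 109059734, minus strand) stood at 32.8, 44.0 and 46.2 TPM in CTRL-IgG replicates 1, 2 and 3, and at 45.7, 36.2 and 44.1 TPM in CTRL-ICB. It stood at 56.0, 65.5 and 66.3 TPM in KO-IgG replicates 1, 2 and 3, and at 56.2, 63.5 and 72.2 TPM in KO-ICB. The KO mean was 63.5 ± 7.11 TPM (SD, n = 4) and the CTRL mean 41.5 ± 5.60 TPM (SD, n = 6), with all 4 KO tumours above all 6 CTRL tumours (exact two-sided permutation p = 0.00476, the smallest that 210 splits allow). Within each treatment the exact permutation test gave p = 0.1, the smallest that 10 splits allow. The log2 fold change of Trex1 was 0.61 ± 0.16 (SE), with a limma adjusted p of 0.18 over all genes, and of 0.027 over the 12 libraries. Insertions and deletions made by Cas9 can leave a transcript in place, host cells in the tumour keep an intact Trex1, and the gene lies inside the annotated span of Atrip (109057933 to 109074124), with which it can share reads. Atrip stood at 7.81 to 13.6 TPM in KO libraries, highest in KO-IgG replicate 1, and at 7.17 to 9.69 TPM in CTRL libraries. The transcript level therefore does not check the label in the direction of a loss, and each direction below belongs to tumours labelled TREX1 KO.

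**Figure D1:**
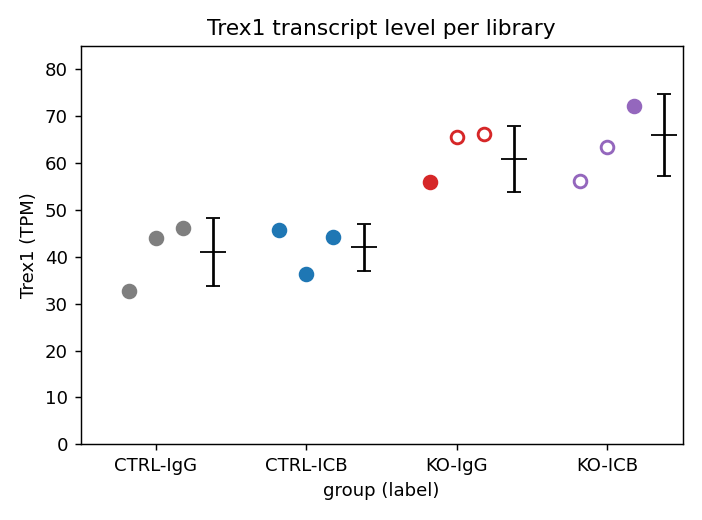
Trex1 level (TPM, linear axis from 0) in each of the 12 libraries by labelled group, where open circles are the libraries averaged in pairs and bars show mean ± SD over tumours. The 6 libraries labelled TREX1 KO lie between 56.0 and 72.2 TPM, above the 6 CTRL libraries, which lie between 32.8 and 46.2 TPM.

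Averaged over both treatments, tumours labelled TREX1 KO held more transcript of lymphocyte effector genes than CTRL tumours, and less S100a8 and Il1r2, genes of neutrophils. Ccl5, a chemokine that attracts T cells and NK cells, rose to 178 ± 39.8 TPM (SD, n = 4) from 44.4 ± 15.3 TPM (n = 6), a log2 fold change of 2.03 ± 0.28 (SE). Ifng, which encodes interferon gamma, rose to 7.49 ± 0.558 from 1.90 ± 0.590 TPM, and Ctsw, a cathepsin of cytotoxic lymphocytes, rose to 19.7 ± 2.26 from 6.82 ± 0.854 TPM. S100a8, a subunit of the neutrophil protein calprotectin, fell to 19.3 ± 8.57 from 197 ± 86.7 TPM, a log2 fold change of -3.26 ± 0.45. Il1r2, a decoy receptor for interleukin 1 made by neutrophils, fell to 3.62 ± 0.577 from 13.8 ± 3.35 TPM.

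These were among 15 genes that passed an adjusted p of 0.05 in limma, 10 higher and 5 lower, of 13886 tested. Sema3b, a secreted semaphorin, rose by 2.35 ± 0.30 on the log2 scale, from 12.3 ± 7.56 to 61.3 ± 13.3 TPM. Apol7c (2.26 ± 0.30), Kctd12b (2.25 ± 0.26) and Dok2, an adaptor of immune cell signalling (1.72 ± 0.23), rose as well. Fcer1a, the alpha chain of the IgE receptor of mast cells and basophils, rose from 4.02 ± 1.24 to 16.3 ± 4.09 TPM. Cfb, complement factor B, rose from 57.8 ± 7.72 to 129 ± 14.6 TPM, and Uba7, the activating enzyme for ISG15, rose by 1.07 ± 0.15 on the log2 scale. Msln, which encodes the surface protein mesothelin, fell by 1.54 ± 0.17 on the log2 scale from 135 ± 23.8 TPM in CTRL, Ptgfrn fell to 45.7 ± 7.52 from 103 ± 15.4 TPM, and Tle1, a transcriptional corepressor, fell to 10.8 ± 0.652 from 22.6 ± 1.67 TPM. Adjusted p-values of the 15 genes ran from 0.0389 to 0.0480, and every one of them had all 4 KO tumours on 1 side of all 6 CTRL tumours. Apol7c belongs to a multigene family whose members can share reads. The count was 273 (156 higher, 117 lower) without KO-IgG replicate 1 and 449 (270 higher, 179 lower) over the 12 libraries, and both held all 15 genes. With no filter it was 14, 5 of them among the 15, without the libraries with skin transcripts 9, 3 of them among the 15, and without the averaged KO-IgG pair 16, 2 of them among the 15. It fell to 0 without CTRL-IgG replicate 1 or CTRL-ICB replicate 2, to 1 without CTRL-IgG replicate 2 or KO-ICB replicate 3, to 2 without CTRL-ICB replicate 1 or CTRL-ICB replicate 3, to 0 without the averaged KO-ICB pair or after quantile normalization, and to 7 (4 higher, 3 lower, 5 of them among the 15) after median centring.

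**Figure D2:**
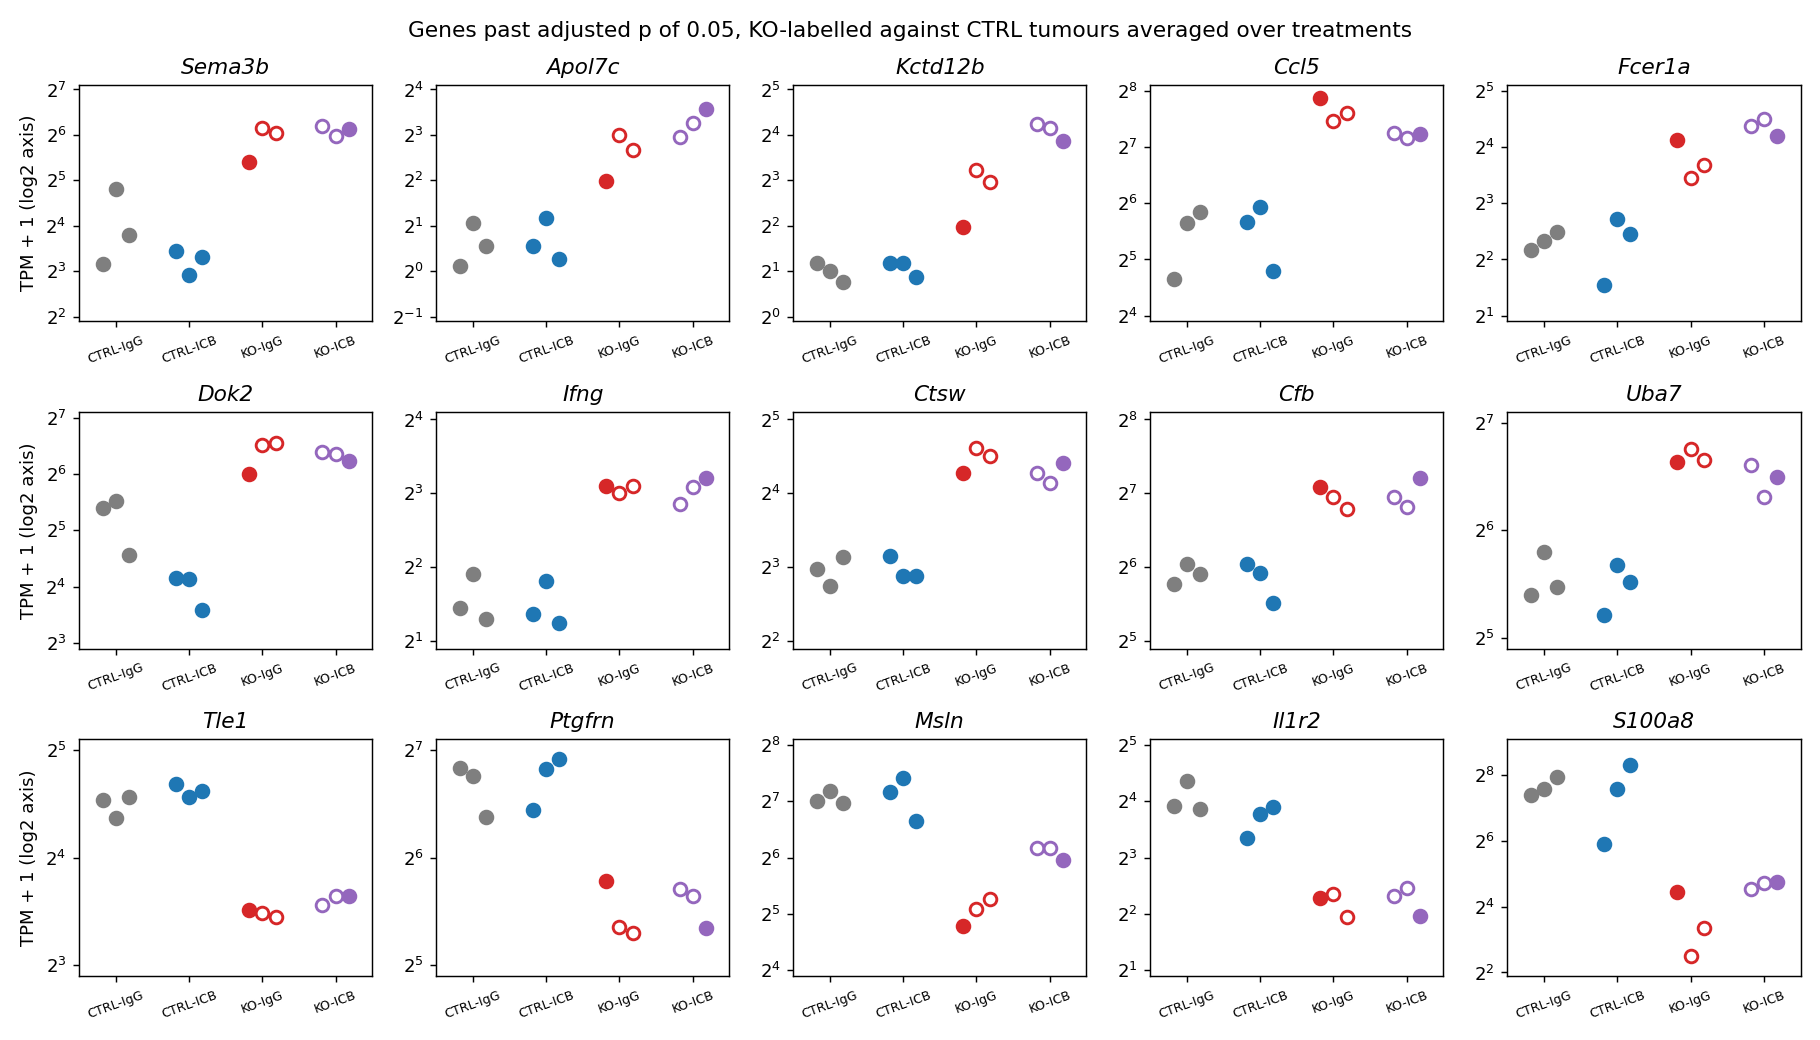
Levels (TPM + 1, log2 axes) of genes that passed the test between tumours labelled TREX1 KO and CTRL tumours, 1 point per library by group, with open circles for the libraries averaged in pairs. Ccl5 lies between 142 and 232 TPM in the 6 KO libraries and between 24.1 and 60.0 TPM in the 6 CTRL libraries.

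Interferon genes lay higher in tumours labelled TREX1 KO. All 35 members of the type I interferon-stimulated list had a positive log2 fold change, with a median of 0.81, and Mx1, an antiviral GTPase, stood at 22.8 ± 11.2 TPM against 7.50 ± 1.80 TPM in CTRL. None of the 35 passed over all genes and 21 rose when adjusted over the list alone. The limma camera test placed the list higher (adjusted p = 4.27e-17 with a preset correlation), a call lost at adjusted p = 0.189 with an estimated correlation. KO-IgG replicate 1 did not share the rise, with Isg15, a ubiquitin-like interferon-induced protein, at 140 TPM against 548 to 754 TPM in the other 5 KO libraries and 132 to 248 TPM in CTRL, and without it the list median was 1.20. Interferon-gamma-induced genes had a median of 0.44, with 6 of 25 members higher when adjusted over the list alone (adjusted p = 0.212 with an estimated correlation). Igtp, an interferon-induced GTPase, stood at 317 ± 47.3 TPM against 161 ± 39.3 TPM. MHC class II genes, which present antigen to CD4 T cells, had a median of 0.64 with 7 of 13 higher when adjusted over the list alone (adjusted p = 0.155 with an estimated correlation), and H2-Ab1 stood at 2389 ± 323 TPM against 1230 ± 265 TPM. MHC class I genes had a median of 0.28, with 5 of 20 higher when adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). Cytosolic nucleic acid sensing genes had a median of 0.32, with 2 of 24 higher when adjusted over the list alone (adjusted p = 0.155 with an estimated correlation), and Sting1, the adaptor of DNA sensing, stood at 91.0 ± 6.44 TPM against 65.3 ± 11.2 TPM (log2 fold change 0.49, adjusted p = 0.29). H2 genes belong to a multigene family whose members can share reads.

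Markers of cytotoxic lymphocytes rose in tumours labelled TREX1 KO. Cytotoxic effector genes had a median log2 fold change of 1.36 over 12 members, of which Ifng and Ctsw passed over all genes and 9 rose when adjusted over the list alone. NK cell genes had a median of 1.23 over 10 members, of which 9 rose when adjusted over the list alone and 0 passed over all genes by limma (adjusted p of Ncr1, an NK cell receptor, 0.0558). Ncr1 stood at 8.04 ± 2.60 TPM against 1.51 ± 0.814 TPM. Of the 25 lists called by camera in this comparison, 14 higher and 11 lower of 35 tested, these 2 held with an estimated correlation, with an adjusted p of 0.034 for cytotoxic effector genes and 0.00947 for NK cells. The rotation test fry called 9 lists.

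T cell genes had a median of 0.87, with 14 of 19 higher when adjusted over the list alone (adjusted p = 0.155 with an estimated correlation), and the median was 0.49 without KO-IgG replicate 1. Cd3g, a chain of the T cell receptor complex, stood at 35.6 ± 17.2 TPM against 13.4 ± 3.74 TPM. Lymphocyte-attracting chemokines had a median of 0.76 (0.36 without KO-IgG replicate 1), with Ccl5 past the test over all genes and 3 of 13 higher when adjusted over the list alone (adjusted p = 0.155 with an estimated correlation). Checkpoint and exhaustion genes had a median of 0.33, with 1 of 11 higher when adjusted over the list alone (adjusted p = 0.315 with an estimated correlation), and without KO-IgG replicate 1 the median was 0.09 and the call was lost at adjusted p = 0.0894. Dendritic cell genes had a median of 0.68 (0.28 without KO-IgG replicate 1), with 3 of 11 higher when adjusted over the list alone (adjusted p = 0.155 with an estimated correlation). Mast cell and basophil genes had a median of 1.55, with Fcer1a past the test over all genes, and 6 of 8 higher and 1 lower when adjusted over the list alone (adjusted p = 0.155 with an estimated correlation). Neutrophil genes had a median of -0.73, with S100a8 and Il1r2 past the test over all genes, and 5 of 11 lower and 1 higher when adjusted over the list alone (adjusted p = 0.212 with an estimated correlation). S100a9, the partner of S100a8, stood at 55.3 ± 26.1 TPM against 337 ± 156 TPM (adjusted p = 0.109).

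Several lists of stromal and other genes had negative medians, and of these the epithelial-mesenchymal transition list was also called by fry. Fibroblast and matrix genes had a median of -0.87 with all 18 members negative and 2 lower when adjusted over the list alone (adjusted p = 0.23 with an estimated correlation). Dcn, the matrix proteoglycan decorin, stood at 13.7 ± 2.02 TPM against 45.3 ± 26.1 TPM. Epithelial-mesenchymal transition genes had a median of -0.41 with 4 of 13 lower when adjusted over the list alone (adjusted p = 0.128 with an estimated correlation, 0.016 by fry). Vim, the intermediate filament of mesenchymal cells, stood at 310 to 608 TPM in the other 5 KO libraries and at 2188 TPM in KO-IgG replicate 1, against 1199 to 2869 TPM in CTRL. Inflammatory cytokine genes of the NF-kB pathway had a median of -0.24 with 2 of 23 lower when adjusted over the list alone (adjusted p = 0.495 with an estimated correlation), and the call was lost at adjusted p = 0.103 without CTRL-IgG replicate 2 and 0.065 without CTRL-ICB replicate 2. Ptgs2, the inducible cyclooxygenase, stood at 6.97 ± 2.30 TPM against 27.6 ± 13.3 TPM. Hypoxia and glycolysis genes had a median of -0.43 with 0 of 20 passing limma when adjusted over the list alone (adjusted p = 0.457 with an estimated correlation).

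Transcripts of other tissues and signs of RNA composition moved with the groups as well. Skeletal muscle genes had a median of 0.75 with 6 of 13 higher when adjusted over the list alone (adjusted p = 0.128 with an estimated correlation), and they were high in the KO-ICB libraries. Mitochondrially encoded transcripts had a median of 0.67 with 1 of 13 higher when adjusted over the list alone (adjusted p = 0.212 with an estimated correlation), and took 3.55% to 7.53% of the TPM in KO libraries against 2.59% to 4.74% in CTRL libraries. Heat shock genes (median -0.26, adjusted p = 0.223 with an estimated correlation), integrated stress genes (-0.28, adjusted p = 0.22 with an estimated correlation) and immediate early genes (-0.25, adjusted p = 0.458 with an estimated correlation) were called lower by camera, and these calls were lost without KO-IgG replicate 1 (adjusted p = 0.193, 0.0596 and 0.398). Endothelial genes (median -0.45, adjusted p = 0.457 with an estimated correlation) and erythroid genes (-0.65, adjusted p = 0.427 with an estimated correlation) were called lower too, and missed the threshold without CTRL-ICB replicate 1 (adjusted p = 0.0749 and 0.115), erythroid genes also without CTRL-IgG replicate 2 (0.0593). None of the members of these 5 lists passed limma when adjusted over the list alone. Skin keratinocyte genes had a median of -2.77 (adjusted p = 0.474 with an estimated correlation), a call lost at adjusted p = 0.139 without CTRL-IgG replicate 3 and 0.237 without KO-IgG replicate 1. Krt5, a keratin of basal keratinocytes, stood at 328 TPM in CTRL-IgG replicate 3 and at 770 TPM in CTRL-ICB replicate 3, and at most at 17.2 TPM in the other libraries. The 4T1 epithelial genes had a median of -0.26 and were not called (adjusted p = 0.327), while without KO-IgG replicate 1, where the KO-IgG group is the averaged pair alone, the median was 0.41 (adjusted p = 0.0034 at the preset correlation). Epcam, an epithelial adhesion molecule, stood at 0.661 TPM in KO-IgG replicate 1 and between 87.1 and 1239 TPM in the other libraries.

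**Figure D3:**
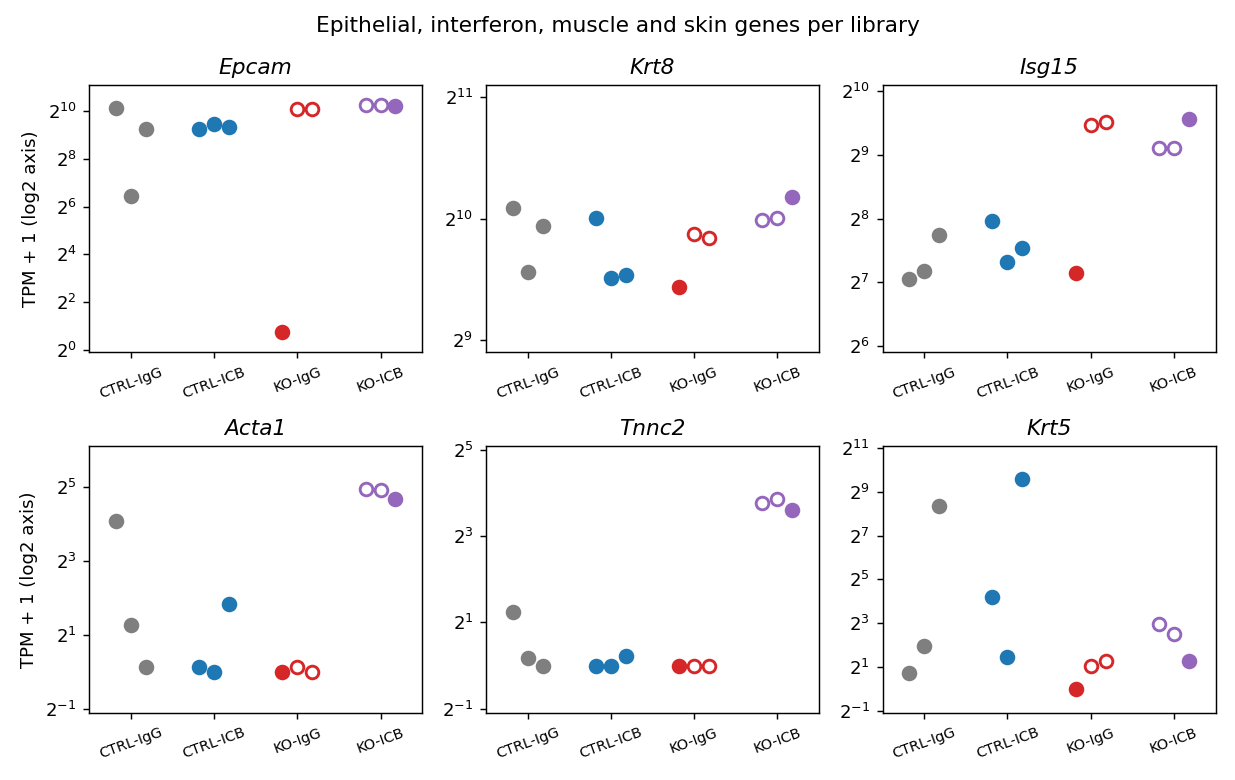
Levels (TPM + 1, log2 axes) of Epcam, Krt8, Isg15, Acta1, Tnnc2 and Krt5 in the 12 libraries by group, with open circles for the libraries averaged in pairs. Epcam is lowest in KO-IgG replicate 1 at 0.661 TPM, and Krt5 is highest in CTRL-IgG replicate 3 and CTRL-ICB replicate 3 at 328 and 770 TPM.

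Under isotype antibodies, tumours labelled TREX1 KO held more NK cell and cytotoxic transcript than CTRL tumours. NK cell genes rose as a list, with a median log2 fold change of 1.42 and 6 of 10 members higher when adjusted over the list alone (adjusted p = 0.00892 with an estimated correlation). Klrd1, an NK cell receptor chain, stood at 32.4 ± 20.5 TPM (SD, n = 2) against 6.88 ± 2.26 TPM (n = 3), a log2 fold change of 1.98 ± 0.41 (SE). Cytotoxic effector genes rose as a list, with a median of 1.24 and 6 of 12 higher when adjusted over the list alone (adjusted p = 0.0267 with an estimated correlation). Gzmb, a granzyme of killer lymphocytes, stood at 69.9 ± 8.34 TPM against 17.3 ± 10.7 TPM. T cell genes had a median of 1.11 with 11 of 19 higher when adjusted over the list alone (adjusted p = 0.108 with an estimated correlation), and the median was 0.44 without KO-IgG replicate 1. Neutrophil genes had a median of -1.20 with 3 of 11 lower when adjusted over the list alone (adjusted p = 0.108 with an estimated correlation), and fibroblast and matrix genes of -1.25 with 0 of 18 positive (adjusted p = 0.212 with an estimated correlation).

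No single gene passed the test in this comparison: limma called 0 genes, 715 had an unadjusted p under 0.05, near the 5% that chance gives, and the smallest adjusted p was 0.113, for Msln (132 ± 10.7 TPM in CTRL-IgG, 30.9 ± 6.10 TPM in KO-IgG). The next smallest belonged to S100a8 (log2 fold change -3.95 ± 0.64), the histone gene H3c13 (-2.02 ± 0.31), Il1r2 (-1.83 ± 0.29) and Ctsw (1.47 ± 0.25), each with an adjusted p of 0.345. MHC class I genes had a median of 0.33 with 17 of 20 members positive and 0 passing by limma when adjusted over the list alone (adjusted p = 0.108 with an estimated correlation, 0.0437 by fry). Nlrc5, the transactivator of MHC class I genes, had a log2 fold change of 0.91 ± 0.34 (adjusted p = 0.85). Type I interferon-stimulated genes had a median of 0.57 with 30 of 35 positive and 0 passing by limma when adjusted over the list alone (adjusted p = 0.352 with an estimated correlation). Without KO-IgG replicate 1 that median was 1.23, while the list level of KO-IgG replicate 1 was -0.48, inside the range of the CTRL-IgG tumours (-0.67 to 0.12). Ifit2, an interferon-induced RNA-binding protein, stood at 27.1 ± 2.69 TPM against 13.7 ± 4.32 TPM. The 4T1 epithelial genes were among the lists called lower (median -0.97, adjusted p = 0.435 with an estimated correlation), and without KO-IgG replicate 1 their median was 0.51 with the averaged pair as the lone KO-IgG tumour (adjusted p = 0.0041 at the preset correlation). Of the lists on RNA quality, mitochondrially encoded transcripts had a median of 1.02 with 13 of 13 positive and 10 higher when adjusted over the list alone (adjusted p = 0.108 with an estimated correlation, 0.0933 by fry). Heat shock genes (median -0.40, adjusted p = 0.108 with an estimated correlation) and immediate early genes (-0.46, adjusted p = 0.352 with an estimated correlation) were called lower by camera, with 0 members passing limma when adjusted over the list alone. Camera called 25 lists in all, 15 higher and 10 lower. Over the 12 libraries 16 genes passed (6 higher, 10 lower), and 1 passed without CTRL-ICB replicate 3, which enters through the shared estimate of spread.

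Under checkpoint antibodies, tumours labelled TREX1 KO held more skeletal muscle transcript than CTRL tumours. Tnnc2, the troponin C of fast skeletal muscle, rose to 12.2 ± 1.30 TPM (SD, n = 2) from 0.0564 ± 0.0977 TPM (n = 3), a log2 fold change of 3.64 ± 0.39 (SE, limma adjusted p = 0.0417). Skeletal muscle genes rose as a list, with a median of 1.80, all 13 members positive and 11 higher when adjusted over the list alone (adjusted p = 0.049 with an estimated correlation). Ckm, the creatine kinase of muscle, stood at 9.83 ± 5.63 TPM against 0.373 ± 0.133 TPM. NK cell genes rose as a list too, with a median of 1.14 and 6 of 10 higher when adjusted over the list alone (adjusted p = 0.0208 with an estimated correlation). Mast cell and basophil genes had a median of 2.05 with 6 of 8 higher when adjusted over the list alone (adjusted p = 0.205 with an estimated correlation), and endothelial genes of -0.76 with 0 of 14 passing limma when adjusted over the list alone (adjusted p = 0.402 with an estimated correlation). Erythroid genes (median -1.24, adjusted p = 0.364 with an estimated correlation) and skin genes (-2.82, adjusted p = 0.672 with an estimated correlation) were called lower by camera as well, skin genes not without CTRL-ICB replicate 3 (adjusted p = 0.698), KO-IgG replicate 1 (0.104) or KO-ICB replicate 2 (0.0566).

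Tnnc2 was the 1 gene that passed, and 1108 genes had an unadjusted p under 0.05. Ncr1 stood at 9.13 ± 1.52 TPM against 1.05 ± 0.248 TPM. Cytotoxic effector genes had a median of 1.25 with 4 of 12 higher when adjusted over the list alone (adjusted p = 0.063 with an estimated correlation, 0.0216 by fry). Gzmb stood at 98.6 ± 5.78 TPM against 29.3 ± 18.1 TPM, and Ifng at 7.55 ± 0.935 TPM against 1.82 ± 0.612 TPM. Type I interferon-stimulated genes had a median of 1.13 with all 35 positive and 18 higher when adjusted over the list alone (adjusted p = 0.263 with an estimated correlation). Oas1g, a synthetase that activates RNase L and belongs to a multigene family whose members can share reads, had a log2 fold change of 1.75 ± 0.41 (adjusted p = 0.335), and Zbp1, a sensor of nucleic acids, stood at 269 ± 37.2 TPM against 145 ± 26.9 TPM. Camera called 20 lists, 13 higher and 7 lower. The count of genes was 15 (14 higher, 1 lower) without KO-IgG replicate 1, 40 (28 higher, 12 lower) over the 12 libraries, 74 (57 higher, 17 lower) with only the groups compared, 1263 (715 higher, 548 lower) with array weights, and 2 without CTRL-IgG replicate 3 or KO-IgG replicate 3. It was 0 without CTRL-IgG replicate 2, CTRL-ICB replicate 1, CTRL-ICB replicate 2 or KO-ICB replicate 3, and Tnnc2 also missed the threshold without CTRL-ICB replicate 3 (adjusted p = 0.0922), at a filter of 5 TPM (0.338) and with a pseudocount of 0.1 (0.325).

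**Figure D4:**
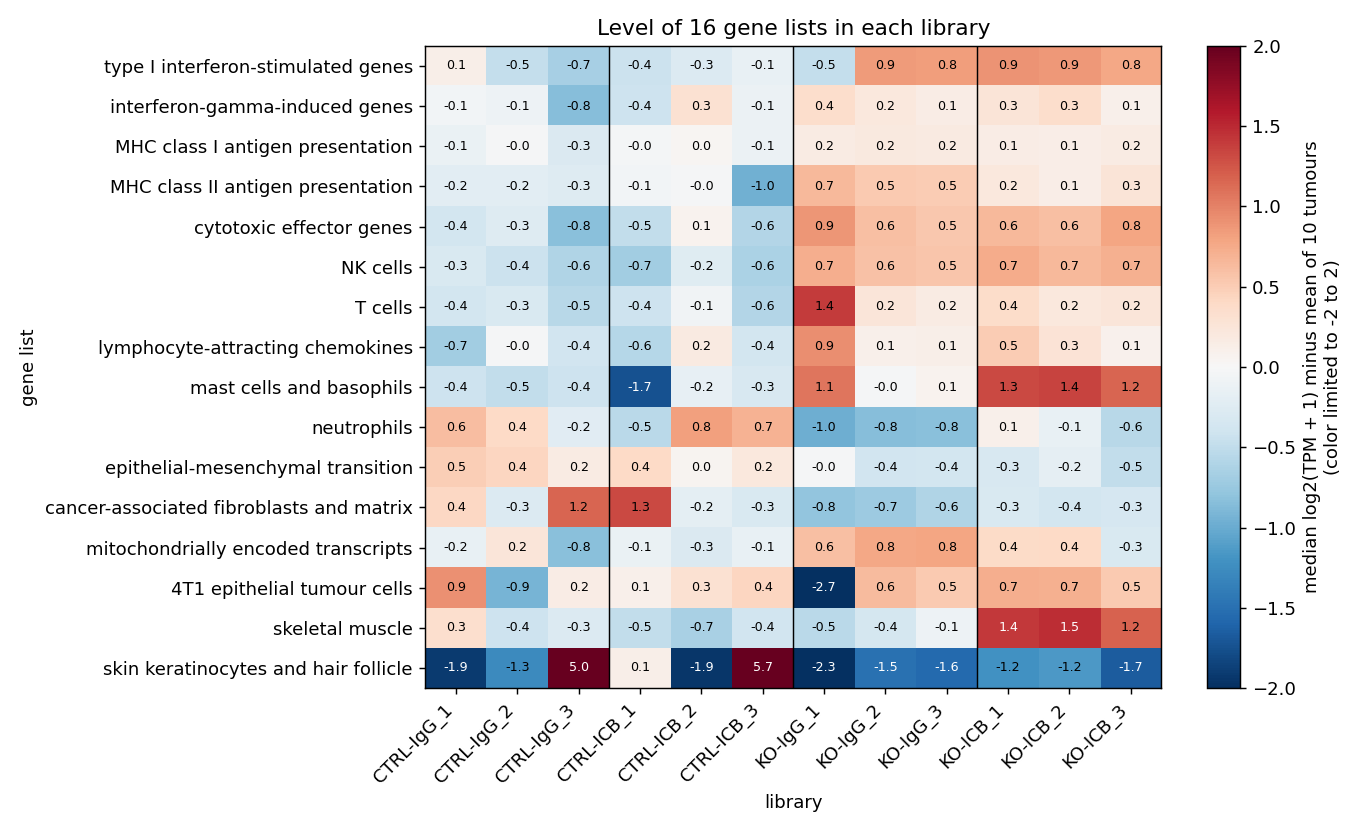
Level of a selection of the fixed gene lists in each library, with the colour scale in log2 units. Each value is the median over list members of log2(TPM + 1) minus the gene's mean over the 10 tumours. KO-IgG replicate 1 stands at -0.48 for type I interferon-stimulated genes, where the other 5 KO libraries stand between 0.77 and 0.91, and skeletal muscle genes stand at 1.19 or higher in the KO-ICB libraries.

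In CTRL tumours, no gene passed the test between checkpoint and isotype antibodies. The genes with the smallest p were H1f2 and H2ac18, which encode histones, Dok2, the RNA export receptor Nxf1 and the cytoskeletal gene Add2. H2ac18 had a log2 fold change of 1.54 ± 0.33 (SE) between 3 CTRL-ICB and 3 CTRL-IgG tumours, and H1f2 of 0.76 ± 0.16, each with an adjusted p of 1 by limma. Dok2 stood at 14.8 ± 3.24 TPM (SD, n = 3) against 36.2 ± 11.9 TPM (n = 3). Trex1 had a log2 fold change of 0.04 ± 0.20.

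Limma called 0 genes in that comparison and 176 had an unadjusted p under 0.05, fewer than 5% of the 13886 tested. Camera called 5 lists, none of which held with an estimated correlation. Interferon-gamma-induced genes (median 0.26, adjusted p = 0.849 with an estimated correlation), MHC class I genes (0.12, adjusted p = 0.533 with an estimated correlation) and erythroid genes (0.78, adjusted p = 0.533 with an estimated correlation) lay higher. Cell cycle genes (median -0.26, adjusted p = 0.849 with an estimated correlation) and skeletal muscle genes (-0.32, adjusted p = 0.578 with an estimated correlation) lay lower, and 0 members of the 5 lists passed limma when adjusted over the list alone. The number of lists called was 3 without CTRL-IgG replicate 1, 12 without CTRL-IgG replicate 2, 8 without CTRL-ICB replicate 1 and 15 without CTRL-ICB replicate 3. The interferon-gamma-induced list missed the threshold without CTRL-IgG replicate 3 (adjusted p = 0.538) or CTRL-ICB replicate 2 (0.526), the MHC class I list without CTRL-IgG replicate 1 (0.266), CTRL-IgG replicate 3 (0.069), CTRL-ICB replicate 1 (0.111) or CTRL-ICB replicate 2 (0.167), the cell cycle list without CTRL-ICB replicate 2 (0.134), and the muscle list without CTRL-IgG replicate 1 (0.0761).

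In tumours labelled TREX1 KO, checkpoint antibodies went with more skeletal muscle transcript. Skeletal muscle genes had a median log2 fold change of 1.85 between KO-ICB and KO-IgG, with all 13 members positive and 8 higher when adjusted over the list alone (adjusted p = 0.0837 with an estimated correlation, 0.013 by fry). Tnnc2 stood at 12.2 ± 1.30 TPM (SD, n = 2) in KO-ICB and was listed at 0 in KO-IgG (n = 2). Atp2a1, the calcium pump of fast muscle, stood at 3.64 ± 0.833 TPM against 0.193 ± 0.189 TPM, and Hp, the plasma protein haptoglobin, at 46.1 ± 28.8 TPM against 5.27 ± 2.26 TPM. Limma called 0 genes, 443 had an unadjusted p under 0.05, fewer than the 5% that chance gives, and the smallest adjusted p was 0.0784, for Tnnc2.

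Camera called 17 lists between KO-ICB and KO-IgG, 9 higher and 8 lower, and 0 of them held with an estimated correlation. Mitochondrially encoded transcripts had a median of -0.68 with 0 of 13 positive (adjusted p = 0.641 with an estimated correlation). Several of the lists moved with KO-IgG replicate 1, without which the KO-IgG group is the averaged pair alone. The 4T1 epithelial genes had a median of 1.61 (adjusted p = 0.641 with an estimated correlation) and of 0.15 without it, where the call was lost at adjusted p = 0.892. Type I interferon-stimulated genes had a median of 0.65 (adjusted p = 0.641 with an estimated correlation), and without KO-IgG replicate 1 the direction of the test turned (adjusted p = 0.225). T cell genes had a median of -0.59 (adjusted p = 0.641 with an estimated correlation), and without KO-IgG replicate 1 the direction turned as well (adjusted p = 0.892). Over the 12 libraries 3 genes passed, all higher, and 1 passed without CTRL-IgG replicate 1, while 8 lists were called without KO-IgG replicate 1.

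The interaction, the antibody effect in tumours labelled TREX1 KO minus that in CTRL tumours, was positive for skeletal muscle genes. Their median difference was 2.02 on the log2 scale, with all 13 positive and 10 higher when adjusted over the list alone (adjusted p = 0.037 with an estimated correlation). Des, the intermediate filament of muscle, stood at 4.26 ± 2.31 TPM in CTRL-IgG and 1.83 ± 0.181 TPM in CTRL-ICB (SD, n = 3 each), and at 2.28 ± 0.501 TPM in KO-IgG and 11.1 ± 3.67 TPM in KO-ICB (n = 2 each). Ckm had a difference of 2.90 ± 0.53 (SE) and Add2 of 2.96 ± 0.66, both with an adjusted p of 0.999. Limma called 0 genes, 196 had an unadjusted p under 0.05, again fewer than 5%, and the smallest adjusted p was 0.301, for Tnnc2. Camera called 17 lists, 9 higher and 8 lower, of which muscle alone held with an estimated correlation. Mitochondrially encoded transcripts had a median difference of -0.74 with 0 of 13 positive (adjusted p = 0.607 with an estimated correlation), and 4T1 epithelial genes of 1.26 (adjusted p = 0.647 with an estimated correlation), whose direction turned without KO-IgG replicate 1 (adjusted p = 0.293). Over the 12 libraries 1 gene passed, and 8 lists were called without KO-IgG replicate 1.

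Across the 13886 genes, which are not independent replicates, the effects of the KO label under the 2 treatments were positively correlated. The log2 fold changes of KO-ICB against CTRL-ICB and of KO-IgG against CTRL-IgG, which share no library, had a Pearson r of 0.463 and a Spearman rho of 0.431, and 65.9% of genes had the same sign. Simulated groups without an effect gave a mean r of 0.00422, and the covariance was 0.133 against 0.000852 simulated. The simulation drew each gene independently, whereas genes of real tumours can vary together. It therefore cannot say how large an r arises without an effect. Without KO-IgG replicate 1 the r was 0.682, and with KO-IgG replicate 1 as the lone KO-IgG tumour it was 0.0414. The effect of the KO label under isotype antibodies and the antibody effect in CTRL tumours, which share the CTRL-IgG libraries, had an r of 0.0585 and a rho of 0.0218. Simulated groups without an effect gave an r of 0.446 there, and the covariance was 0.00903 against 0.0803 simulated, a difference of -0.0713. The r of that pair was -0.0327 without CTRL-ICB replicate 1, -0.0601 without CTRL-ICB replicate 2, and 0.254, 0.321, 0.284, 0.260 and 0.203 without CTRL-IgG replicates 1, 2 and 3, CTRL-ICB replicate 3 and KO-IgG replicate 1. The observed r and covariance lie below those that the shared libraries gave in that simulation, which has the limit given above. The 3 CTRL-IgG libraries cannot be split into parts of at least 2, so their part in these values could not be removed.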

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

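The tests on held-out genes, V segments and further muscle genes were chosen before their results were seen, and the tests on epithelial genes, on NK cell and cytotoxic genes, on lymphoid tissue genes and on other splits of the tumours after. For V segments and further muscle genes the condition that a value must pass its bound by more than its spread was added after the values were seen: both values met the bound against the explanation as it was first written.

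The antibody effect on skeletal muscle genes differed between genotypes, with a median interaction of 2.02 on the log2 scale (camera adjusted p = 0.037 with an estimated correlation). Muscle lying beside the tumour and taken with it is a candidate source, since the 3 KO-ICB libraries hold Acta1, the actin of skeletal muscle, at 29.5, 28.8 and 24.2 TPM, while CTRL-IgG replicate 1 holds 15.9 TPM and the other 8 libraries at most 2.54 TPM. Of 11 further skeletal muscle genes, 5 (Myl1, Pgam2, Casq1, Myoz1 and Cox6a2) were higher in both KO-ICB tumours than in each of the other 8, where chance gives 2.22% per gene (Eno3, a muscle enolase at 95.6 to 114 TPM there, reached 173 TPM elsewhere). This is too few to decide for or against muscle tissue. Dissection and treatment cannot be told apart for these genes, because the transcripts come in both tumours of 1 group, and an effect of the antibodies in tumours labelled TREX1 KO stays open as untested.

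KO-IgG replicate 1 stands apart from the other KO libraries in type I interferon-stimulated and epithelial genes. Measured against the other KO tumours, a lower share of tumour cells alone is argued against, since epithelial genes did not fall by a common amount. That holds only if host cells make none of these genes, which was not tested. The gap between the most and the least lowered of 16 genes was 8.91 on the log2 scale, against at most 0.84 between the other KO tumours. Epcam stood at 0.661 TPM and Krt8, a keratin of simple epithelia, at 692 TPM. The CTRL tumours were not part of that yardstick, and they differed unevenly too. Epcam and Krt8 stood at 87.1 and 754 TPM in CTRL-IgG replicate 2, and at 1113 and 1086 TPM in CTRL-IgG replicate 1. On 100 genes chosen without KO-IgG replicate 1, that library lay nearer the KO mean on 19. CTRL tumours held out in the same way gave 7 to 35 and the other KO tumours 54, 81 and 90. Those genes had the smallest p and were not chosen as interferon genes. On them a control tumour under a KO label stays possible. Trex1 at 56.0 TPM lies above the 46.2 TPM of the highest CTRL library, and is the lowest of the KO libraries. Its level does not check the label, and Atrip, with which it can share reads, is highest in this library at 13.6 TPM. The type I interferon-stimulated list was not tested in this way, and its level of -0.48 in KO-IgG replicate 1 lies inside the CTRL range (-0.67 to 0.12). A swapped label would hold for the whole library, not for 1 set of its genes. A swapped label alone leaves the epithelial genes unexplained, of which 16 of 16 lay below every CTRL tumour. They lay below every other KO tumour too, so they cannot tell which genotype the library has. For NK cell and cytotoxic genes 17 of 22 lay above every CTRL tumour. Those lists were picked after they had been called higher in KO tumours, this library among them. Its T cell (1.39), B and plasma cell (2.26) and macrophage (1.06) list levels are above those of each other library. These genes therefore cannot tell a KO tumour from a CTRL tumour with more immune transcript, and a swapped label stays open. Lymphoid tissue in the sample stays open, with 4 of 8 measured lymphoid genes (Cxcl13, Ccr7, Cd22 and Ltb) above every other tumour, and a change in the tumour cells themselves was not tested.

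The pairs of near-identical libraries, KO-IgG replicates 2 and 3 and KO-ICB replicates 1 and 2, may each be RNA of 1 tumour measured in both libraries. V segments of antibodies and T cell receptors are used differently in each animal, and their levels correlated within the pairs at 0.492 (KO-IgG) and 0.672 (KO-ICB), against -0.0660 to 0.543 in the other 64 library pairs. The lower value lies inside that range, which the spread of a correlation over 108 segments does not settle. At matched expression, other genes gave a median correlation of 0.608 (0.0896 to 0.874) for the KO-IgG pair and 0.651 (0.179 to 0.894) for the KO-ICB pair. Only the segments of annotated length detected in each pair were matched, 41 and 36 rather than 108. Over these, V segments gave 0.160 and 0.448, inside those ranges. A shared tumour and a pair of very similar ones cannot be told apart here, and the count of genes in the averaged comparison was 449 rather than 15 with the libraries counted separately.

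Other splits of the tumours bear on the gene counts. In the averaged comparison 4 of 100 splits, the real one included, gave 15 genes or more, a share under 0.05, with 276 as the highest of the others, while the count itself was 0 after quantile normalization, so chance is not firmly excluded. The splits that gave more, 276 with CTRL-IgG replicate 3 and 89 with CTRL-IgG replicate 1 in the place of KO-IgG replicate 1, and 61, point to a structure of the samples: the first and second of these keep the other KO tumours together, and with the labels as given 273 genes passed without KO-IgG replicate 1. For KO-IgG against CTRL-IgG 10 of 10 splits gave at least the real 0 genes (limma, highest other 94), for KO-ICB against CTRL-ICB 3 of 10 gave at least the real 1 (highest other 1), and for CTRL-ICB against CTRL-IgG 10 of 10 gave at least the real 0 (highest other 1). Those splits are too few for a share under 0.05, and where the real count is 0 any split reaches it.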

How the results depend on the processing

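Leaving out pairs or the libraries with skin transcripts, counting 12 libraries and leaving out mitochondrial genes were alternatives chosen after seeing the data. The others were fixed beforehand, the replicate number as a block among them, though fitting it over the 12 libraries was decided after. Depth cannot be read from TPM, so its effect on low genes is unknown.

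The gene count for KO-IgG against CTRL-IgG (0) was 10 with no filter, 1 with only the groups compared, 16 over the 12 libraries and 44 without the averaged KO-IgG pair. For KO-ICB against CTRL-ICB (1) it was 4 without trend and robust shrinkage, 5 with no filter, 0 at 5 TPM, 0 with a pseudocount of 0.1, 74 with only the groups compared, 1263 with array weights, 40 over the 12 libraries, 0 without the libraries with skin transcripts, 15 without the averaged KO-IgG pair and 0 without the averaged KO-ICB pair. For KO-ICB against KO-IgG (0) it was 1 after quantile normalization, 1 after median centring, 2 without trend and robust shrinkage, 13 with no filter, 3 over the 12 libraries and 221 without the averaged KO-IgG pair. For the interaction (0) it was 9 with no filter, 1 over the 12 libraries and 7 without the averaged KO-IgG pair. For the averaged comparison (15) it was 0 after quantile normalization, 7 after median centring, 30 with array weights, 449 over the 12 libraries, 9 without the libraries with skin transcripts and 0 without the averaged KO-ICB pair. Leaving out each replicate in turn gave 0 to 1, 0 to 15, 0 to 1 and 0 to 273 genes for KO-IgG against CTRL-IgG, KO-ICB against CTRL-ICB, KO-ICB against KO-IgG and the average. It gave 0 to 0 for the interaction and for CTRL-ICB against CTRL-IgG. Where the library left out belonged to an averaged pair, its partner stayed as that sample. The ranges here and below therefore do not cover the loss of a paired sample, which the alternatives without a pair show. The cause of these changes was not tested.

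With the replicate number as a block (replicate block, 12 libraries), 2 genes passed for KO-IgG against CTRL-IgG, 8 for KO-ICB against CTRL-ICB, 2 for KO-ICB against KO-IgG and 259 in the averaged comparison, fewer in each than over the 12 libraries without it. The 18 pairs of libraries with the same number deviated from their groups with correlations of -0.364 to 0.270, 5 of them over 0.1. Of 12 libraries, 3 correlated best with their own number. This gives no sign that the numbers pair the tumours, but deviations within groups of 3 libraries, with near-identical pairs among them, cannot exclude it. Trex1 averaged over treatments was 0.60 over the 12 libraries with an adjusted p of 0.044 with the block and 0.027 without it, and 0.53 to 0.66 leaving out each replicate.

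The number of lists called with an estimated correlation and by fry was 2 and 3 for KO-IgG against CTRL-IgG (25 at the preset), 2 and 3 for KO-ICB against CTRL-ICB (20), 0 and 0 for CTRL-ICB against CTRL-IgG (5), 0 and 1 for KO-ICB against KO-IgG (17), 1 and 1 for the interaction (17) and 2 and 9 for the average (25). It was 11 for CTRL-ICB against CTRL-IgG without the libraries with skin transcripts and 9 for KO-ICB against KO-IgG without the averaged KO-IgG pair. Leaving out each replicate gave 18 to 27, 18 to 21, 3 to 15, 8 to 17, 8 to 20 and 21 to 26 lists in that order of comparisons.

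Trex1 changed sign where it was near 0. CTRL-ICB against CTRL-IgG was -0.17 with array weights and -0.11 to 0.14 leaving out each replicate, KO-ICB against KO-IgG was -0.021 to 0.15, and the interaction was -0.016 with the block, -0.016 over the 12 libraries and -0.064 to 0.22. The direction of a list turned, with the adjusted p given, for type I interferon-stimulated genes in KO-IgG against CTRL-IgG without the averaged KO-IgG pair (0.0455, with 1 tumour left in the group), for 4T1 epithelial genes in the average over the 12 libraries (0.992) and for fibroblast and matrix genes in the interaction without the libraries with skin transcripts (0.269).

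Without KO-IgG replicate 1 the direction turned as follows, with its adjusted p and then the range over leaving out each replicate. In KO-IgG against CTRL-IgG it turned for 4T1 epithelial genes (0.0041, 1.08e-05 to 0.0218) and cell cycle genes (0.253, 0.00541 to 0.615), and in the average for 4T1 epithelial genes (0.0034, 0.0034 to 0.616). In the interaction it turned for 4T1 epithelial genes (0.293, 8.83e-07 to 0.293), cell cycle genes (0.935, 1.86e-05 to 0.935) and type I interferon-stimulated genes (0.0945, 8.81e-08 to 0.0945). In KO-ICB against KO-IgG it turned for type I interferon-stimulated genes (0.225, 4.12e-09 to 0.225), T cell genes (0.892, 8.53e-06 to 0.892), macrophage genes (0.922, 0.00335 to 0.922) and ribosomal protein genes (0.313, 0.0196 to 0.900, the last without KO-ICB replicate 3, where it turned too). Skin genes in KO-IgG against CTRL-IgG turned without CTRL-IgG replicate 3 (0.980, 1.02e-05 to 0.980). The cause was not tested.

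The r of the effects that share CTRL-IgG libraries was -0.0950 without the averaged KO-IgG pair, 0.392 without the libraries with skin transcripts and -0.0601 to 0.321 leaving out each replicate. The r of the KO effects was 0.595 over the 12 libraries, 0.349 without the libraries with skin transcripts, 0.0414 without the averaged KO-IgG pair and 0.344 to 0.682 leaving out each replicate. Of the alternatives of 166 results for named genes, 3874 values kept direction and side of the threshold, 205 passed it, 197 missed it and 11 turned, all of these Trex1. Of those of 110 results for lists, 2037 kept both, 1 passed, 362 missed it and 15 turned. For 291 further results for genes that are not named, set aside after this account had been seen, 19 values turned.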

Other observations

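None of the values here comes from a test of a hypothesis, and all of them were chosen after they had been seen.

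KO-IgG replicate 1 held several transcripts of immune cells at higher levels than the other libraries. Timd4, a phosphatidylserine receptor of tissue macrophages, stood at 18.7 TPM there and at most at 1.34 TPM in the other 11 libraries. Cd8a, the coreceptor of cytotoxic T cells, stood at 23.7 TPM against 3.49 to 10.7 TPM, and Cxcl9, a chemokine induced by interferon gamma, at 234 TPM against 42.7 to 109 TPM. Arg1, an arginase of myeloid cells, was lowest there at 78.6 TPM, against 125 to 640 TPM in the others.

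Spp1, which encodes osteopontin, stood between 1472 and 1999 TPM in the 5 other KO libraries and at 3804 TPM in KO-IgG replicate 1, against 1711 to 6178 TPM in CTRL. Ifnb1, which encodes interferon beta, stayed under 1 TPM in all 12 libraries, with its highest value of 0.934 TPM in KO-IgG replicate 1. Trex2, a paralog of Trex1 made in skin, stood at 13.2 TPM in CTRL-IgG replicate 3 and 60.7 TPM in CTRL-ICB replicate 3, the libraries with skin transcripts, and at most at 0.174 TPM elsewhere. The predicted gene Gm12895 stood at 17903 TPM in CTRL-ICB replicate 2, the highest of any gene in that library, and at 3184 to 7232 TPM in the others. CTRL-IgG replicate 2 held Epcam at 87.1 TPM, below every other library but KO-IgG replicate 1.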
